A study of Caenorhabditis elegans with 24 samples.

How the data were processed

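Gene expression was measured in young adult Caenorhabditis elegans hermaphrodites of the laboratory wild type N2 and of a plep-1 mutant strain, on 24 Agilent arrays with a colour for each of 2 channels. Per the labels, worms were synchronised as arrested larvae, and labelled RNA of each sample in Cy5 was hybridised against a pooled reference in Cy3 on every array, with no dye swap. A dye effect common to all arrays cancels in the difference between genotypes. Each genotype had 12 arrays, which the titles number by hybridisation (3) and by a rep number (4). The design text states 3 biological and 4 technical replicates, without naming either number as the biological one. What separated the biological replicates is not given in the sources used here, so p-values measure only the spread between the samples as defined below, which may be technical.

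Per the file headers, the scanner files were made with Feature Extraction 10.7.3.1. The deposited scanner files hold the median intensity of both channels for each spot, local background intensities, processed signals and a log10 ratio of Cy5 over Cy3. Median intensities were used in place of the mean intensities assumed beforehand, which the files used here do not hold. The other deposited columns used are marks for control spots, outliers, saturation and spots well above background. The authors' value table holds log2 ratios, and limma is the tool that the submitters' processing notes name. The scale, centring and direction of the value table were found by setting each column against the scanner files. The slope on the best matching array lay between 0.789 and 0.992, column medians lay between -0.006 and 0.0083, and the direction was Cy5 over Cy3. Which normalization gave these values stays unknown. Across genes, the lowest correlation between any pair of arrays was -0.213 in scanner values and -0.263 in the value table.

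Of 43603 distinct probes that are not controls, 34544 (79.2%) were matched to a gene by sequence name or accession in a RefSeq table of assembly WBcel235, which gave 19859 genes, and 9059 probes were not matched. The arrays were designed on another genome build, so no coordinates are given, and the RefSeq table served for names, chromosomes and the order of neighbouring genes. The position test used runs of 50 neighbouring genes in place of the windows in bases chosen beforehand. Median Cy5 intensities per array lay between 130 and 925 against local backgrounds of 47.5 to 57.0, and 63.3% to 83.7% of spots were well above background in Cy5. The number of arrays limits the precision.

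Scanner intensities were background corrected with normexp (offset 50) and normalized by loess within arrays, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as outliers were left out (7 to 12439 per array). Probes entered where Cy5 was well above background on at least 50% of the arrays of 1 genotype, and a gene was represented by its brightest probe, which left 16137 genes. The fit chosen before the data were examined takes each scanner file under the sample it is attached to and the hybridisation as the replicate, with the mean of 4 arrays as 1 sample and 3 samples per genotype. Genes were tested with limma's lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05. A total of 33 gene lists written before the data were examined, and the 6 chromosomes, were tested with limma's camera at a preset correlation of 0.01. Lists were also tested with an estimated correlation and with fry.

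The rule for named genes, also fixed beforehand, takes plep-1 and the 12 genes with the largest rise and the 12 with the largest fall among those that pass, have separated groups and are well above background in both genotypes. Where fewer pass, it takes the smallest unadjusted p up to that number, given as not passing. It further takes the 3 members of each list with the smallest unadjusted p, and genes well above background on at least 50% of arrays of 1 genotype and on no array of the other. Of the second fit described below, only 3 genes per direction are named, a number reduced after the results were seen.

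The scanner files and the value table differ on which array belongs to which sample. Each of the 24 value table columns matched 1 scanner file of the same hybridisation, each a different one, with r between 0.975 and 0.999 over 33127 probes centred across arrays, and at most 0.904 for the second best file. No column matched the file attached to its own sample (0 of 24). In 16 columns, those of hybridisations 2 and 3, the matching file is attached to a sample of the other genotype. In the value table, arrays of 1 genotype with the same rep number deviated together across hybridisations (mean r = 0.766 across probes), and arrays that share only the hybridisation did not (mean r = -0.270). With scanner files as attached, the mean r for the same rep number was 0.221. A second fit therefore uses the value table with the rep number as the replicate and the 3 hybridisations averaged, 4 samples per genotype. It changes the labels and the replicate together. It was chosen after these checks. Its results on single probes and on genes had been seen before it was listed as an alternative and before it was placed beside the fit chosen beforehand.

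In all, 47 settings were fitted: the one chosen as the main result, 27 alternatives chosen before the data were examined and 19 chosen after seeing the data. All 10 splits of the 6 samples, all 35 splits of the 8 samples and all 16 fits without 1 sample of each genotype were also run. Versions of some of these fits on single probes had been seen before they were listed. For named genes, a change of sign between fits in which the gene passed in neither was not counted as a reversal. This was decided after the results were seen, and it applies to 472 such changes. Camera was used for each setting's list tests, except that cameraPR on z values was used for fits with duplicateCorrelation or with trend and robust. On simulated data with the spread of the real genes, 200 of 16137 genes changed 2-fold were recovered at 97.5% for the scanner files as attached and at 94.0% for the value table. At a fold of 1.5, 87.5% and 61.0% were recovered. These shares apply only where the labels of a set are right. Labels that mix the genotypes would cancel part of a real change and widen the spread within groups. In that case the shares for the scanner files as attached do not measure what that fit could detect.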

Results

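The data are log2 ratios of Cy5 over a common Cy3 reference for N2, the laboratory wild type of C. elegans, and for a plep-1 mutant strain, in young adult hermaphrodites, with 12 arrays for each genotype. The comparison between the genotypes asks which transcripts differ in the mutant. The deposited scanner files and the value table put different arrays under the same sample, and neither is known to be right, so genotypes are given as labelled throughout. Each result is given for the scanner files as attached (3 samples per genotype, 1 per hybridisation) and for the authors' value table (4 samples per genotype, 1 per rep number). Genes with signal in 1 genotype alone are the exception, given under the attached labels only.

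The plep-1 transcript, measured by 1 probe, did not pass the test between the genotypes as labelled in either set. It passed in opposite directions under other settings, with a difference of -0.55 in the value table with the hybridisation as the replicate and of 0.35 in the scanner files as attached with array weights. Both settings take the hybridisation as the replicate. Within hybridisations 1, 2 and 3 of the value table the difference was -0.75, -0.43 and -0.48. The genotypes of hybridisations 2 and 3 are exchanged between the sets, so the opposite directions are largely fixed by the labels. In the scanner files as attached the log2 ratio of plep-1 was 0.04 ± 0.33 (SD, n = 3) in samples labelled N2 and 0.08 ± 0.35 (SD, n = 3) in samples labelled plep-1, a difference of 0.04 with a standard error of 0.21 (limma adjusted p of 1.00). In hybridisation 1 the sample labelled N2 was the higher, at 0.42 against -0.32. In hybridisations 2 and 3 the sample labelled plep-1 was the higher, at 0.23 against -0.19 and at 0.34 against -0.10.

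Over the value table samples, plep-1 was at 0.33 ± 0.52 (SD, n = 4) in samples labelled N2 and at -0.23 ± 0.37 (SD, n = 4) in samples labelled plep-1, a difference of -0.55 with a standard error of 0.26 (limma adjusted p of 0.996). Replicates 2, 3 and 4 labelled N2 stood at 0.54, 0.85 and 0.30, and replicates 1, 2 and 3 labelled plep-1 at -0.47, -0.48 and -0.26. Replicate 1 labelled N2 stood at -0.38 and replicate 4 labelled plep-1 at 0.31, each among the values of the other genotype. The allele, and whether the probe lies in an altered part of the gene, are not given in the sources used here, and a probe outside an altered part checks nothing.

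**Figure D1:**
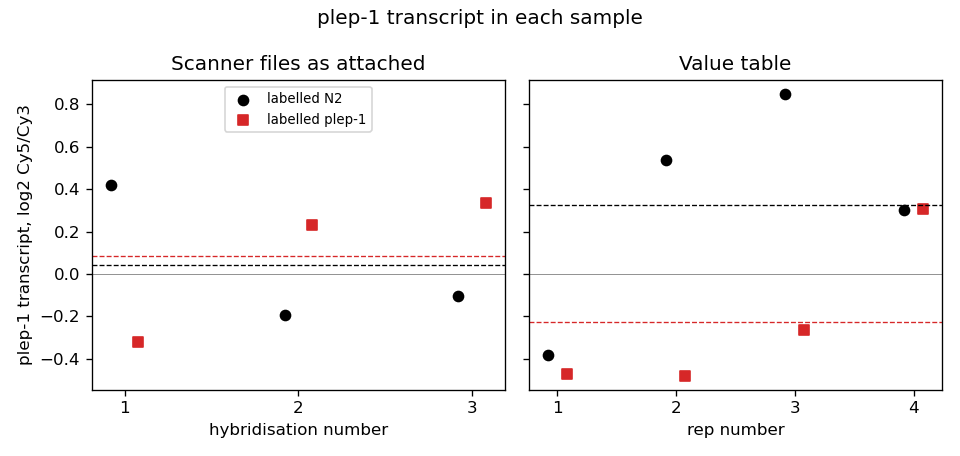
The plep-1 transcript (log2 Cy5 over Cy3, vertical axis) in each sample labelled N2 (circles) or plep-1 (squares), by hybridisation number for the scanner files as attached and by rep number for the value table, with group means as dashed lines. In the value table, replicate 1 labelled N2 lies at -0.38 and replicate 4 labelled plep-1 at 0.31.

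No gene passed the test between the genotypes as labelled in either set. Of 16137 genes tested with limma in the scanner files as attached, 0 were higher and 0 lower in samples labelled plep-1, and 60 had an unadjusted p under 0.05, where chance alone gives about 807. Other splits of the same 6 samples gave 68 to 7928. Labels that mix the genotypes would cancel differences and widen the spread within groups, so the shortfall is no evidence that the genotypes are alike. For the value table, 0 were higher and 0 lower, and 479 had an unadjusted p under 0.05. With the hybridisation as the replicate, an alternative chosen beforehand, the value table gave 6475 genes (4017 higher and 2458 lower in samples labelled plep-1), and array weights on the scanner files as attached gave 5364. The 6475 genes count only if the hybridisation is the biological replicate, which the sources used here do not state. The stated number of biological replicates equals that of the hybridisations, and the fit by rep number has more samples per genotype than stated. Value table arrays of the same genotype and rep number deviated together across hybridisations (mean r = 0.766). Arrays sharing only the hybridisation had a mean r of -0.27, and arrays sharing neither number -0.279. These r argue against hybridisations as independent samples, so no result on genotype is drawn from the 6475 genes. The same holds for the 5364 genes, whose fit also takes the hybridisation as the replicate.

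By smallest p in the scanner files as attached, the 12 genes with higher values in samples labelled plep-1 were F23D12.4, F28B4.1, C06E2.1, C27D6.1, oac-8, C25E10.4, C23G10.11, the nuclear hormone receptor gene nhr-16, F56H11.6, C16D9.4, Y54G2A.41 and K08E7.6. The 12 with lower values were dma-1, a receptor for dendrite branching, F07G6.9, gex-2, srh-164, nipa-1, asd-1, cgef-1, H05C05.2, C25B8.8, lin-29, a heterochronic transcription factor, srsx-20 and F53B1.8. None of these 24 passed (limma adjusted p of 1.00 for each). Their differences lay between -0.25 for F07G6.9 and 0.40 for C16D9.4.

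Other genes had the smallest p in the value table, and none of them passed. The log2 difference was 0.52 for dbd-5, 0.33 for pgal-1 and 0.37 for scl-2, and -0.36 for K07A1.5, -0.27 for Y71H2AM.20 and -0.35 for snrp-40.2 (limma adjusted p of 0.996 for each). In the scanner files as attached, the differences of dbd-5, pgal-1 and scl-2 were -0.12, -0.10 and -0.15, and those of K07A1.5, Y71H2AM.20 and snrp-40.2 were 0.13, 0.06 and 0.10, each of the opposite sign. Both sets hold the same 24 arrays. The genotypes of the 16 arrays of hybridisations 2 and 3 are exchanged between them, and those of hybridisation 1 are not. A gene with a similar difference in each hybridisation of 1 set must then take a smaller difference of the opposite sign in the other. For such genes the opposite signs are fixed by the labels and are no separate result.

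Signal well above background in 1 genotype alone was seen for 5 genes in the scanner files as attached. B0507.5 was at least 1.15-fold, F52E10.2 at least 1.14-fold, tbx-41 at least 1.12-fold and H10D12.2 at least 1.04-fold higher in samples labelled N2, and ncx-5 at least 1.09-fold higher in samples labelled plep-1. In limma, 0 of these genes passed. Each bound starts from the mean Cy5 level over the arrays of the brighter genotype, including those without signal well above background. It is set against a mean over the other's arrays. On each of those, the larger of the gene's own Cy5 value and the dimmest signal well above background was taken. The same background marks chose the genes. With no dye swap, each bound is open to dye bias that differs between arrays.

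Gene lists had medians of opposite sign between hybridisations of the scanner files as attached. The genotypes of hybridisations 2 and 3 are exchanged between the sets. A list with 1 direction in the value table therefore takes these opposite signs largely by construction. Major sperm proteins, the abundant cytoskeletal and signalling proteins of sperm, had a median difference of -0.15 in hybridisation 1 and of 0.14 in hybridisations 2 and 3 (labelled plep-1 minus labelled N2). Subunits of the vacuolar ATPase, a proton pump, had medians of 0.09, -0.12 and -0.14, and lysozymes and antimicrobial peptides medians of 0.10, -0.10 and -0.12. Chromatin regulators had medians of 0.08, -0.07 and -0.13. Within the value table, the same lists kept 1 direction in hybridisations 1, 2 and 3, at -0.15, -0.15 and -0.13 for major sperm proteins, 0.08, 0.10 and 0.12 for the vacuolar ATPase, 0.10, 0.09 and 0.11 for lysozymes and 0.08, 0.04 and 0.07 for chromatin regulators. If the rep number marks the sample, the hybridisations measure the same samples again, so a shared direction is no independent agreement.

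Over all samples of the value table, the median of major sperm proteins was -0.15, with 0 of 27 members above 0 (camera adjusted p = 2.39e-12, and adjusted p = 0.635 with an estimated correlation). In the scanner files as attached it was 0.03, with 23 of 27 members above 0 (camera adjusted p = 0.00798, and adjusted p = 0.770 with an estimated correlation), and it turned to -0.02 in the sample channel alone. It was also -0.02 without the sample of hybridisation 3 labelled N2 and -0.01 without the sample of hybridisation 2 labelled plep-1, and 0.008 with no pass without that of hybridisation 2 labelled N2. It rose to 0.09 and 0.06 without the samples of hybridisation 1 labelled N2 and plep-1, to 0.07 with median centring or scaling between arrays and to 0.15 with array weights, passing in each. Replicate 1 labelled N2 (-0.045) and replicate 4 labelled plep-1 (0.107) of the value table lay nearer to the other genotype on this list, where the other samples lay between 0.093 and 0.242 for N2 and between -0.107 and -0.048 for plep-1, and without this pair, doubted from its values, the median was -0.24. Members of this family are nearly identical, so their probes need not measure them separately. Among value table differences, msp-64 differed by -0.30, msp-63 by -0.32 and msp-50 by -0.29, and 0 members passed adjusted over the list alone or over all genes. Sperm genes outside this family did not pass in the value table (median -0.008, 15 of 33 members above 0, camera adjusted p = 0.1095). Neither did oocyte and eggshell genes (0.058, camera adjusted p = 0.454) or meiotic prophase genes (0.052, camera adjusted p = 0.612). The shift is thus not shown for sperm genes beyond this family.

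The vacuolar ATPase had a median of 0.12 in the value table, with 16 of 21 members above 0 (camera adjusted p = 0.0166, and 0.629 as adjusted p with an estimated correlation), vha-19 being at 0.28 and vha-1 at 0.21. In the scanner files as attached its median was -0.06, with 2 of 21 above 0 (camera adjusted p = 0.00574, and 0.770 as adjusted p with an estimated correlation), vha-3 being at -0.22 and vha-17 at -0.11. Lysozymes and antimicrobial peptides, effectors of innate immunity, had medians of 0.10 in the value table, with 32 of 45 members above 0, and of -0.05 in the scanner files as attached, with 6 of 45 above 0 (camera adjusted p = 0.00297 and 0.00574, and adjusted p = 0.635 and 0.770 with an estimated correlation). Of these, lys-1 differed by 0.36 in the value table and nlp-33 by -0.14 in the scanner files as attached.

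Chromatin regulators had medians of 0.06 in the value table and -0.04 in the scanner files as attached (camera adjusted p = 0.0134 and 0.0101), and ribosomal proteins medians of -0.03 and 0.02 (camera adjusted p = 0.0188 and 0.00574). With an estimated correlation the adjusted p was 0.635 and 0.770 for chromatin regulators and 0.657 and 0.770 for ribosomal proteins. The ribosomal protein median turned to -0.002 in the scanner files as attached without the sample of hybridisation 3 labelled N2 (camera adjusted p = 0.616), and was -0.007 in the value table without replicate 4 labelled N2 (camera adjusted p = 0.284). The cytochromes P450, with a median of 0.01, passed in the scanner files as attached (camera adjusted p = 0.00574, and adjusted p = 0.770 with an estimated correlation), and their median was below 0 without background correction and in processed signals. Their value table median was -0.02, with 23 of 66 members above 0 (camera adjusted p = 0.0515, not passing), and with the hybridisation as the replicate they passed with this direction (camera adjusted p = 0.0374). Lists that passed in the value table alone, with no test of the difference between the sets, were cuticle collagens (median -0.05), fatty acid metabolism (0.08), phase II transferases (-0.03), vitellogenins (0.16), the endoplasmic reticulum unfolded protein response (0.10) and muscle genes (0.07), with camera adjusted p between 0.00141 and 0.0306. With an estimated correlation their adjusted p was 0.629 for fatty acid metabolism and 0.635 for the others. In the scanner files as attached the medians were 0.01 for cuticle collagens, -0.04 for fatty acid metabolism, 0.002 for phase II transferases, -0.05 for vitellogenins, -0.04 for the endoplasmic reticulum list and -0.03 for muscle genes, and none of these lists passed in the fit chosen beforehand. All but muscle genes passed there under at least 1 other setting. With median centring, collagens (0.02, camera adjusted p = 4.98e-07) and phase II transferases (camera adjusted p = 0.0487, towards higher values although their median was -0.001) passed and the vitellogenin median turned to 0.005. With array weights, collagens, phase II transferases, fatty acid metabolism (-0.08, camera adjusted p = 0.00532) and the endoplasmic reticulum list (-0.09, camera adjusted p = 0.0276) passed, as these 4 did without either sample of hybridisation 1, and vitellogenins passed with scaling between arrays (-0.15, camera adjusted p = 0.0254). For the sample channel alone the median of fatty acid metabolism turned to 0.001. Without replicate 4 labelled N2 the muscle median of the value table was 0.007 (camera adjusted p = 0.585), without replicate 2 labelled N2 that of vitellogenins was 0.06 (0.298), and without replicate 1 labelled N2 that of collagens was -0.03 (0.365). Among their members, col-155 differed by -0.56, lipl-2 by 0.31, vit-1 by 0.27, enpl-1 by 0.22 and tnt-4 by 0.31, and none of these genes passed.

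In all, 6 of 33 lists passed with the preset correlation in the scanner files as attached and 11 in the value table. With an estimated correlation, 0 lists passed in either set, so none of these calls holds there, and fry gave 0 in either set. Leaving out 1 sample ended each of these calls in at least 1 case, except those of major sperm proteins and fatty acid metabolism in the value table. Calls in the scanner files as attached were lost on leaving out either sample of hybridisation 2 or 3, and no call was lost on leaving out a sample of hybridisation 1. Leaving out 1 sample there gave medians from -0.09 (hybridisation 1, N2) to -0.02 (hybridisation 3, plep-1) for the vacuolar ATPase, from -0.08 (hybridisation 1, plep-1) to -0.02 (hybridisation 3, plep-1) for lysozymes and from -0.07 (hybridisation 1, N2) to -0.02 (hybridisation 3, N2) for chromatin regulators. Those of the value table fell to 0.075 for the vacuolar ATPase without replicate 4 labelled plep-1, and without replicate 3 labelled N2 they were 0.11 for chromatin regulators and -0.06 for ribosomal proteins. The highest camera adjusted p was 0.115 for the vacuolar ATPase (without the sample of hybridisation 2 labelled N2), 0.148 for cytochromes P450 (hybridisation 2, plep-1), and 0.0970 for lysozymes and 0.375 for chromatin regulators (both hybridisation 3, plep-1). For the value table it was 0.163 for the vacuolar ATPase and 0.230 for phase II transferases without replicate 4 labelled N2, 0.449 for chromatin regulators without replicate 2 labelled N2, 0.0765 for lysozymes without replicate 1 labelled plep-1 and 0.182 for the endoplasmic reticulum list without replicate 3 labelled plep-1. In each of the 33 lists, 0 members passed adjusted over the list alone in either set. The test compares a list with all other genes, and its direction differed from the sign of the median or mean in 8 lists of the scanner files as attached and 6 of the value table, 0 of which passed. Genes of chromosomes I, II, III, IV, V and X had medians between -0.02 and 0.02, and 0 of 6 chromosomes passed in either set (camera). With 0 genes passing, 0 runs of neighbouring genes were enriched.

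**Figure D2:**
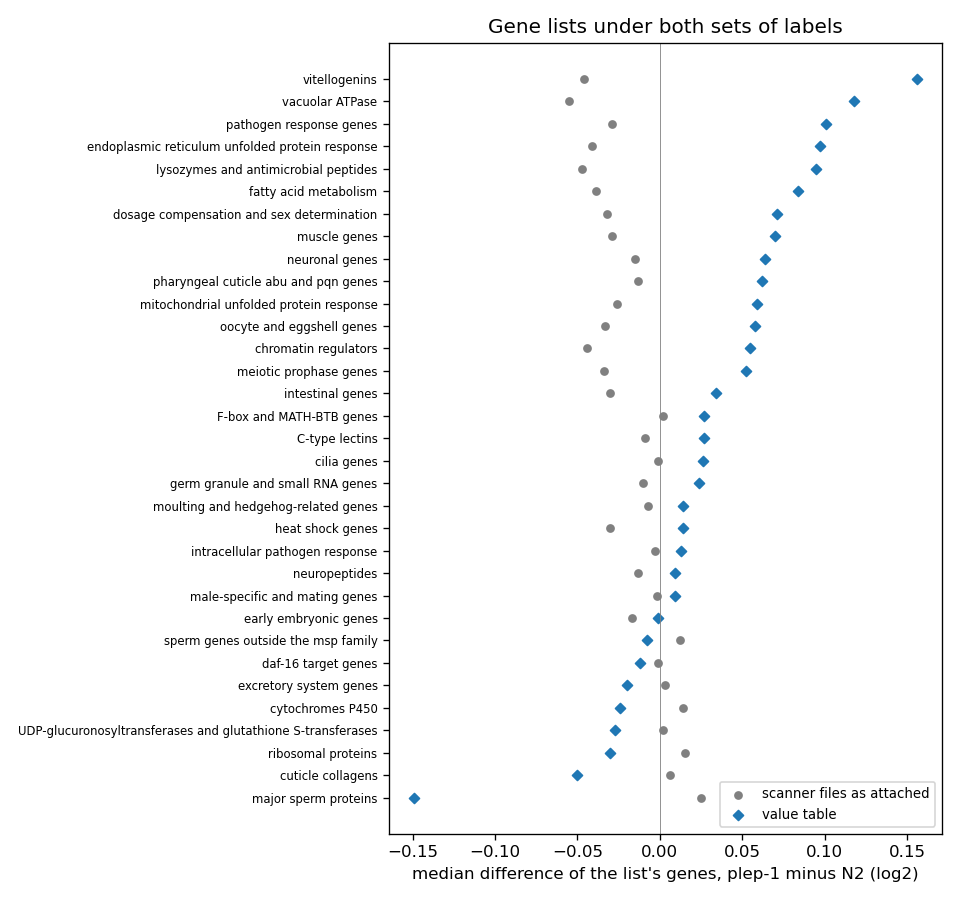
The median log2 difference, labelled plep-1 minus labelled N2, of the genes in each of 33 lists (horizontal axis) for the scanner files as attached (circles) and for the value table (diamonds). Major sperm proteins lie at 0.03 and -0.15, turning to -0.02 in the sample channel alone, and the vacuolar ATPase at -0.06 and 0.12.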

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

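The tests in this part were chosen only after the results were seen, except the count over the 10 splits of the 6 samples. Among 68 groups of 4 value table samples, 2 held a sample far from the others, where chance gives about 1 in 20. Germ granule and small RNA genes had a median of -0.063 in replicate 4 labelled plep-1, and the nearest other sample was at -0.006. Excretory system genes had a median of 0.033 in replicate 3 labelled plep-1, and the nearest other sample was at -0.043.

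The first pattern is that the scanner files and the value table put different arrays under the same sample. A change made by the authors' normalization is argued against only by the match that showed this pattern, which is no separate test. In it, 0 of 24 value table columns matched the file attached to their own sample best. Mislabelling in 1 of the deposits may account for the pattern: the mean correlation of repeat arrays was higher by 0.545 under the value table's labels. The 10 splits of the 6 attached samples are too few for a share under 0.05, and with 0 genes in the real split all 10 give as many by construction. The highest other, which exchanges the genotypes in hybridisations 2 and 3, called 6520. It restores the genotypes of the value table and is the same grouping as the re-linked scanner values by hybridisation. Its count is therefore no separate evidence, and it treats the hybridisations as independent samples. Value table arrays of 1 genotype and rep number had r of at least 0.5745 across hybridisations. Under the attached labels, these same arrays carry 1 genotype in hybridisation 1 and the other in hybridisations 2 and 3. If such arrays repeat 1 sample, the attached labels mix the genotypes, which argues against them as a set. Gene and list counts under the attached labels are then no result on genotype. Whether the value table's own genotypes are right is not settled, and a biological explanation was not tested.

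The second pattern is that replicate 1 labelled N2 and replicate 4 labelled plep-1 of the value table lie with the other genotype in the plep-1 transcript. Of the 16 exchanges of 1 sample between the genotypes, the exchange of this pair called 159 genes and the other 15 called 0, but a regrouping that exchanges 2 samples of each genotype called 891. A difference between hybridisation batches is argued against: of the 100 genes that best separate the exchanged groups in 1 hybridisation, 96.0% to 100% placed each of the pair with the other genotype in the other hybridisations. Arrays with the same rep number deviate together across hybridisations, so genes chosen for another grouping could repeat as well. No other exchange was placed in this way, so these shares do not speak for an exchanged pair. An exchanged pair may explain the pattern, as a hypothesis found and tested on the same data, and so may a structure of the samples unrelated to genotype. No result on genotype is drawn from it, and a biological difference among the samples stays open, untested.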

How the results depend on the processing

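The settings on re-linked scanner values, within hybridisations and on the value table, except the authors' value table with hybridisations as replicates, were chosen after seeing the data. The count of 0 genes held in 40 alternatives. The authors' value table with hybridisations as replicates gave 6475 genes (4017 higher, 2458 lower), with the hybridisation as a replicate block 6909 (4221 and 2688), and scanner values re-linked to samples by the array match, with hybridisations as replicates, 6520 (4436 and 2084). If the rep number marks the biological replicate, these treat repeat hybridisations of the same RNA as independent samples. Array weights on the scanner files as attached gave 5364 (1796 and 3568). Their estimation reported incomplete convergence, and the cause was not tested. This fit also takes hybridisations as replicates, so the same limit holds for its genes and lists. Its major sperm protein median of 0.149 lay near the 0.136 and 0.135 of hybridisations 2 and 3 and far from the -0.154 of hybridisation 1. The 5364 genes are therefore not shown to be separate from the exchanged grouping. Leaving out 1 sample gave 0 to 1 genes, the 1 being Y76B12C.3 (-0.97, chosen after its value was seen), without the sample of hybridisation 1 labelled plep-1. Without replicate 1 labelled N2 and replicate 4 labelled plep-1 of the value table, doubted from their values, 9 genes passed (8 higher, 1 lower); the other 15 pairs of 1 sample per genotype gave 0. The replicate block gave 0 genes in the scanner files as attached and in the value table by rep number. Samples with the same number did not deviate together (r of -0.732, -0.439 and -0.451 by hybridisation in the scanner files as attached, and -0.005, -0.118, -0.320 and -0.316 by rep number in the value table). The exchange of genotypes between the sets in hybridisations 2 and 3 can by itself make the first 3 negative. Both genotypes were also on every slide, so these r cannot tell whether the hybridisation pairs the samples. For the value table by hybridisation no such r was computed.

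The plep-1 level differed by 0.043 in the scanner files as attached. It was -0.554 in the value table with either number as replicate and with each block. It was -0.548 and -0.536 in re-linked scanner values with the rep number and with the hybridisation as replicate, and -0.926 in the re-linked scanner log ratio. Within hybridisations 1, 2 and 3 of the value table the plep-1 level differed by -0.752, -0.430 and -0.481. In the scanner files as attached it was 0.179 with no background correction, 0.202 with processed signals, 0.147 with scaling between arrays, 0.162 in the sample channel alone and 0.228 in the scanner log ratio. It was 0.353 with array weights and -0.012 with slide as a block. In the value table by rep number without the doubted pair it was -0.969. Leaving out 1 sample gave -0.084 to 0.245 in the scanner files as attached. Leaving out replicates 1 to 4 labelled N2 of the value table gave -0.791, -0.483, -0.381 and -0.563, and replicates 1 to 4 labelled plep-1 -0.472, -0.470, -0.542 and -0.732. Opposite signs with a pass were seen for plep-1 (-0.554), dbd-5 (0.515), pgal-1 (0.327), scl-2 (0.370), K07A1.5 (-0.358), Y71H2AM.20 (-0.271) and snrp-40.2 (-0.348) in the value table with hybridisations as replicates, with and without the block, and in re-linked values by hybridisation (-0.536, 0.209, 0.340, 0.377, -0.352, -0.244 and -0.314). For genes with a similar difference in each hybridisation, the exchanged labels fix these opposite signs.

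The count of 6 lists became 0 with no background correction, with scanner processed signals, with an estimated correlation and with fry, 1 with the scanner log ratio, 2 with the sample channel alone, 10 with scaling between arrays, 11 with array weights and 14 with the authors' value table by hybridisation. Without the samples labelled N2 of hybridisations 1, 2 and 3 it was 11, 2 and 3, and without those labelled plep-1 11, 4 and 3. By rep number in the value table it was 11, with and without each block, 0 with an estimated correlation or fry, and 6 to 12 leaving out 1 sample, the lowest without replicate 4 labelled N2. Without the doubted pair it was 7, with medians of -0.239 for major sperm proteins, 0.149 for the endoplasmic reticulum list and 0.046 for the vacuolar ATPase, collagens at 0.008 (adjusted p = 0.922 by limma's camera) and no pass for the vacuolar ATPase (0.329), lysozymes (0.0585), chromatin regulators (0.0945), ribosomal proteins (0.117) and vitellogenins (0.154). It was 13 by hybridisation with the block, 10 and 14 in re-linked values by rep number (vitellogenins lost at 0.0568 as adjusted p by limma's camera) and by hybridisation, 6 in the re-linked scanner log ratio by rep number (lost were the vacuolar ATPase at 0.108, ribosomal proteins and muscle genes at 0.114, vitellogenins at 0.0569 and the endoplasmic reticulum list at 0.105), and 7, 10 and 13 within hybridisations 1, 2 and 3, with no pass in hybridisation 1 for the vacuolar ATPase (adjusted p = 0.0836 by limma's camera), ribosomal proteins (0.0962), the endoplasmic reticulum list (0.0836) and muscle genes (0.0558), and none in hybridisation 2 for vitellogenins (0.0724), phase II transferases (0.0770) and muscle genes (0.0908). Splits with as many genes as the real one, fixed by its 0, were 10 of 10, and 35 of 35 in the value table. Chromosomes kept 0 shifts in all 43 alternatives run, and positions 0. Signal over background limits the dimmest probes.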

Other observations

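The tests in this part were chosen only after the results were seen. Some transcripts took separate levels over the value table samples, and they were chosen after their values were seen. The log2 ratio of scbp-2 was 0.18, -1.17, -1.13 and -0.91 in replicates 1 to 4 labelled N2 and 0.44, 0.32, 0.21 and -1.1 in replicates 1 to 4 labelled plep-1. For smg-5, a gene of nonsense-mediated decay, the values were 0.13, -1.19, -0.95 and -0.71, and -0.01, 0.12, 0.07 and -0.86. For R07C3.13 they were 0.20, -1.58, -2.14 and -1.63, and 0.15, 0.11, 0.16 and -1.58. The levels of scrm-8 ran the other way, at -0.23, 0.52, 0.50 and 0.46, and -0.56, -0.43, -0.38 and 0.26.

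The third pattern is that another split of the 8 value table samples called more genes than the genotypes as labelled did. Differences within and between genotypes were not compared directly. With 0 genes in the real split, all 35 splits of the 8 value table samples give as many by construction, so this count cannot exclude chance. The highest other, replicates 1 and 4 labelled N2 with replicates 2 and 3 labelled plep-1 against the rest, called 891, which points to a structure of the samples. Each of the 8 samples averages the same 3 hybridisations, so a shift common to a hybridisation could not separate them. The mean r between arrays of the same sample in different hybridisations was 0.766. This r also led to the choice of the rep number as the replicate, so it is no separate test. It cannot speak on a batch that goes with the rep number, which was not tested. Stage or germ line content may contribute. The first component within genotypes held 43.2% of the variance, and its Pearson r with the major sperm protein median was 0.526 (exact permutation p = 0.188, n = 8) and Spearman's rho 0.143 (exact permutation p = 0.752, n = 8), with r = 0.442 without the 2 samples farthest out, which leaves this open. The median was not centred within genotypes and the permutations ran over all 8 samples. These values are therefore not the relation within genotypes alone. Only major sperm proteins were set against this component, and the other sperm, oocyte and meiotic lists were not.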
